A study of Mus musculus with 4 samples.

How the data were processed

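Spleens of UVB-exposed wild-type and Trim21-/- mice were pushed through a 70 µm filter to give a cell suspension, and RNA was extracted from it with TRI Reagent, per the labels' protocols. Per the same protocols, 300 ng of total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced as 75 bp single-end reads. A red cell lysis step is not given in the sources used here.

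The authors deposited 1 table of estimated counts per Ensembl gene for 4 libraries, with 25601 rows. The submitters' processing notes name STAR 2.5.0, RSEM 1.2.25, SAMtools 1.18 and the genome build GRCm38, with no role or order. The annotation release and strand setting of the counting are not given in the sources used here. RSEM, the only quantifier named, shares reads between near-identical genes by estimation, and pairs such as Hba-a1 and Hba-a2 all held reads, so the deposited values were treated as estimated (expected) counts. They were already whole numbers, with 0 values off a whole number, so the rounding applied before testing changed none. Counts of near-identical genes (globins, histones, Gbp, H2-Q and Trim30 genes) are uncertain, since an estimate decides how their reads are split. Overlapping genes, and antisense partners, are uncertain for the same reason, as the strand setting is unknown.

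The 92 spike-in rows held 0 counts in all and were left out. Of 25509 gene rows, 25251 were matched by Ensembl identifier to GENCODE release M21 on GRCm38, and the other 258 have no symbol. Another 8139 genes held 0 counts in every library. Immunoglobulin and T cell receptor genes were not analysed here. Library totals ran from 36173694 to 41924885 counts. A count of 0 was taken to allow up to 3 counts. Wilson intervals at 95% are given for shares of single libraries. Intervals and the 3-count floor cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes was 505 for the wild-type pair and 367 for the knockout pair.

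Groups and replicate numbers were taken from the sample titles. The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Gene counts of knockout and wild-type libraries were compared with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter, robust dispersion estimates, the quasi-likelihood F test and Benjamini-Hochberg adjustment over 13532 genes. The main fit held 2 libraries per genotype and 2 residual degrees of freedom. Unless another test is named, an adjusted p is from this edgeR test, and a gene passed when its adjusted p was under 0.05. Fold changes are knockout over wild type with their standard error (SE), and levels are TMM-scaled CPM (counts divided by the scaled library size) with the SD of 2 libraries.

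Of 36 gene lists, the 34 with at least 5 tested members were tested with camera from limma 3.58.1, which asks whether a list ranks above or below other genes. It was run two-sided with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. A list is called shifted when that adjusted p was under 0.05. The correlation was also estimated from the data, which with 2 residual degrees of freedom is imprecise, and fry was run as well. Counts of members that passed are given over all genes and, where they differ, adjusted over the list alone.

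Named genes followed a fixed rule. It took Trim21, then Cgas, Sting1 (Tmem173 in the annotation), Tbk1, Irf3, Irf7, Ddx41, Isg15, Ifit1 and Mx1, whatever their result. It then took the 10 largest rises and 10 largest falls among genes that passed, with both knockout libraries beyond both wild-type libraries and an average log2 CPM of at least 1. Predicted or unnamed genes, pseudogenes and antigen receptor segments were left out there. It also took up to 4 members with the smallest p of each list described, and every gene of a count of 5 or fewer. Not every gene that the rule takes is reported here.

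Calls within 10 Mb of Trim21 were compared with calls elsewhere by Fisher's exact test. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, other low-count filters, non-robust dispersion, the replicate number as a block, each library left out, no haemoglobin or mitochondrial genes, other thresholds and window sizes. Scaling by library totals alone, and values within each replicate number, were added after the data were seen. With 1 library left out, the genotype with a lone library was assumed to vary like the other genotype's pair. Common dispersion was 0.14 in the main fit, 0.087 without wild-type library 1 or 2 and 0.20 without knockout library 1 or 2. Calls gained or lost in such fits thus depend on which pair's spread was used. With 1 library left out, or with the block, 1 residual degree of freedom remained, so these fits lean more on spread pooled over genes. The weight of that pooled spread (median prior degrees of freedom) was 5.41 in the main fit, and 29.7 and 187 without wild-type library 1 or 2. It was not finite with the block or without a knockout library.

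The tests were tried on 5 simulations of knockout against wild type over 13532 genes, with 200 changed genes each. The edgeR test recovered 2% of genes changed 2-fold, 53.6% at 4-fold, 95.6% at 8-fold and 100% at 16-fold. Of its calls in those simulations, 3.65% were false, against 14.3% for DESeq2. Camera found 5 of 5 simulated shifted lists and called 0 of 100 unshifted lists. Simulated genes were drawn independently and the lists filled at random, so this does not measure false calls among correlated genes. Estimated inter-gene correlations in the data were 0.34 for cell cycle, 0.56 for neutrophil, 0.58 for erythroid and 0.70 for histone genes.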

Results

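Transcripts were measured in splenocytes of UVB-exposed mice, 2 libraries from wild-type mice and 2 from mice that the labels give as Trim21-/-, called knockout below. Trim21 is an E3 ubiquitin ligase and intracellular antibody receptor, and the Ro autoantigen of lupus and Sjögren's disease. The mice were 8 weeks old, were shaved on the back and were given UVB at 100 mJ/cm2. The labels name exposures of 1 or 3 weeks without saying which these mice received. Wild-type libraries held 39501119 and 36173694 counts, and knockout libraries 38383781 and 41924885. Unexposed mice were not analysed here, so every value compares genotypes under UVB. The labels do not say whether the libraries of a genotype came from separate mice. If they did not, p-values would measure only the spread between these samples. In each genotype, however, library 1 had almost no Xist (0.051 CPM in wild type, 0.026 in knockout) and library 2 had 1203 and 296 CPM. Counts of Y-linked genes had the opposite distribution, 122 and 72.1 CPM in libraries 1 and 0 in libraries 2. Each genotype thus had 1 library of male and 1 of female pattern, so its 2 libraries did not come from the same mouse. The main fit held no term for this pattern, so a list with 0 genes passing in it is weak evidence of no change. With the replicate number as a block, which also separates the 2 patterns, 15 of 18 B cell and 18 of 21 T cell genes passed as lower. Of 55 type I interferon-stimulated genes, 5 then passed as higher and 23 as lower.

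The comparison asks which spleen transcripts differ after UVB between mice labelled Trim21-/- and wild type, with DNA sensing and inflammation as the stated interest of the study. In knockout spleens 19 of 26 neutrophil, 16 of 31 erythroid and 34 of 40 cell cycle genes rose, and 0 fell. Mpo, the myeloperoxidase of primary granules, rose from 10.7 ± 5.90 to 807 ± 97.9 CPM (SD, n = 2 per genotype). Klf1, an erythroid transcription factor, rose from 24.1 ± 10.6 to 574 ± 256 CPM, and Birc5, which encodes the mitotic protein survivin, from 26.6 ± 5.18 to 475 ± 179 CPM. B and T cell markers ranked lower as groups (camera adjusted p 4.9e-06 and 4.7e-07, and adjusted p = 0.36 with an estimated correlation for each), with 0 members passing singly over all genes by edgeR. Adjusted over the list alone, 12 B cell and 13 T cell genes fell. With 1 library left out, list medians ranged from -1.28 to -1.06 for B cells and from -1.31 to -0.86 for T cells. Type I interferon-stimulated genes did not rise together: Isg15 rose, Ifit1bl1 fell, and the other 53 of 55 did not pass. Of the 55, 3 passed as higher and 13 as lower without wild-type library 1, and 4 and 14 without wild-type library 2.

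The targeted gene was still counted in the knockout. Trim21 (ENSMUSG00000030966, GRCm38 chromosome 7, 102557921 to 102565486, minus strand) had 1237 and 1912 counts in wild type and 345 and 882 in knockout. Its level was 34.4 ± 9.19 CPM against 16.9 ± 4.94 CPM (n = 2), a log2 fold change of -1.02 ± 0.42 (SE) with an adjusted p of 0.17. Without wild-type library 1 the log2 fold change was -1.29 with an adjusted p of 0.020. The labels do not say which exons the allele lacks, so a count over the whole gene does not check the genotype.

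Across all genes, 851 of 13532 passed, 798 higher and 53 lower in the knockout. Both knockout libraries lay beyond both wild-type libraries for 60.3% of tested genes, where chance gives 33.3% for a gene taken alone. Genes varied together, with 70% of the variance between libraries along a single axis, so that gap is not a test. Of the 798 rises, 84 belonged to the neutrophil, erythroid, cell cycle, histone, and mast cell, basophil and eosinophil lists, which held 143 tested genes. The count moved to 4347 without wild-type library 1 and to 2099 without wild-type library 2, and the falls moved to 2047 and 593, or to 30 without knockout library 1 and 227 without knockout library 2. Scaling by library totals alone gave 782 higher and 1376 lower, as it moved the median log2 fold change of all genes from -0.056 to -0.56.

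Neutrophil genes shifted up. All 26 tested members were higher in the knockout, 19 passed (24 adjusted over the list alone), and the median log2 fold change was 4.89, or 4.46 between libraries 1 and 5.68 between libraries 2. Camera gave an adjusted p of 3.5e-38, and the adjusted p = 0.36 with an estimated correlation. Serine proteases of primary granules rose, Prtn3 by 7.02 ± 0.82 on the log2 scale, Elane by 6.75 ± 0.90 and Ctsg by 6.34 ± 0.69 (SE), with adjusted p of 0.011 to 0.012. Secondary granule genes rose as well, among them Camp (6.47), the cathelicidin gene, Ngp (6.39) and Lcn2 (6.18). Ly6g, the surface marker of mouse granulocytes, rose from 0.90 ± 0.10 to 51.3 ± 4.79 CPM. Fcnb and Mmp8 rose by 6.52 and 4.22, and outside the list Ms4a3, a marker of granulocyte and monocyte progenitors, rose by 6.84. Among the genes with the largest rises was also Tac2 (6.38 ± 0.73), which encodes a tachykinin, with levels of 0.39 ± 0.20 and 33.1 ± 21.4 CPM.

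Erythroid genes were also all higher, 31 of 31 tested, with a median log2 fold change of 3.16 (4.82 between libraries 1, 2.37 between libraries 2). Of these, 16 passed (27 adjusted over the list alone), and 25 passed without wild-type library 2, where the median was 4.57, above the neutrophil median of 4.37. The camera test of the list had an adjusted p of 2.0e-23, and the adjusted p = 0.36 with an estimated correlation. Gata1, a master regulator of red cell formation, rose from 13.4 ± 3.05 to 267 ± 99.6 CPM (adjusted p 0.011), and Epor, the erythropoietin receptor, from 7.61 ± 2.11 to 149 ± 68.0 CPM. Car1, a carbonic anhydrase of erythroid precursors, rose by 3.76 ± 0.48 and Klf1 by 4.58 ± 0.61 on the log2 scale. Haemoglobin genes took 8.25% (95% Wilson interval 8.24 to 8.26) and 4.03% (4.02 to 4.03) of wild-type counts. They took 30.7% (30.6 to 30.7) and 14.9% (14.9 to 14.9) of knockout counts. The megakaryocyte and platelet list did not shift (median 0.55, camera adjusted p 0.079, or 0.039 with no filter, and 3 up and 1 down adjusted over the list alone). Its members Nfe2, a factor shared with the erythroid lineage, and Gp9 rose by 3.59 and 3.50, and Gp9 had an adjusted p of 0.062 without knockout library 1. That list had 4 members higher and 2 lower past the threshold without wild-type library 1, and 4 and 1 without wild-type library 2.

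Cell cycle genes rose almost throughout: 40 of 40 were higher, 34 passed (36 adjusted over the list alone), with a median of 2.67 (3.08 between libraries 1, 2.45 between libraries 2). Camera gave an adjusted p of 1.6e-35, and the adjusted p = 0.36 with an estimated correlation. The mitotic genes Ube2c and Birc5 rose by 4.13 ± 0.49 and 4.16 ± 0.51, and the kinases Cdk1 and Aurka by 3.76 ± 0.46 and 3.58 ± 0.42. Replication-dependent histone genes, transcribed in S phase, were higher in 29 of 29 cases with a median of 2.95 (3.0 and 2.1 between libraries 1 and 2). Of these 7 passed (17 adjusted over the list alone), and camera gave an adjusted p of 2.7e-09, with the adjusted p = 0.46 with an estimated correlation. Hist1h4i and Hist1h2bj rose by 2.95 and 4.40, and Hist1h4i had an adjusted p of 0.056 without knockout library 1. Histone calls numbered 22, 17 and 17 without wild-type library 1, wild-type library 2 or knockout library 2, and 3 without knockout library 1.

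Genes of mast cells, basophils and eosinophils shifted up, with 16 of 18 higher, 8 that rose (10 up and 1 down adjusted over the list alone) and a median of 1.90 (1.5 between libraries 1, 2.5 between libraries 2). Camera gave an adjusted p of 1.1e-07, and the adjusted p = 0.36 with an estimated correlation. The basophil proteases Mcpt8 and Prss34 rose by 4.77 ± 0.49 and 5.64 ± 0.60. The eosinophil peroxidase Epx rose by 3.75 ± 0.55 and the carboxypeptidase Cpa3 by 3.14 ± 0.47. Members that did not pass included Fcer1a (2.08), Ms4a2 (1.72), Siglecf (0.84), Kit (0.23), Ccr3 (0.20) and Cd200r3 (-0.092). Il5ra was lower (-1.72, adjusted p 0.087).

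**Figure D1:**
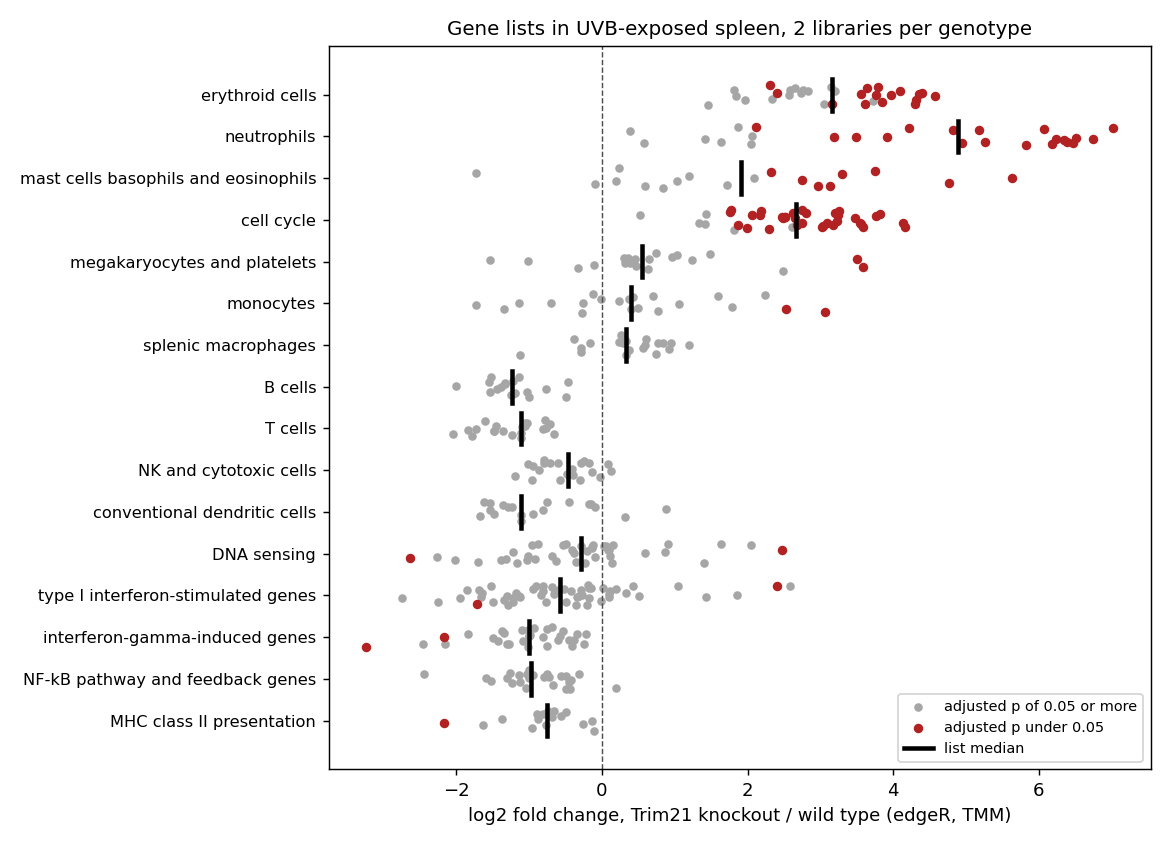
Log2 fold changes (knockout over wild type, x axis) of the tested members of 16 gene lists, with red points for genes with an adjusted p under 0.05 and black bars for list medians. Erythroid, neutrophil and cell cycle medians lie at 3.16, 4.89 and 2.67, and B and T cell medians at -1.24 and -1.11.

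The DNA-sensing list did not shift (41 tested, median -0.28, camera adjusted p 0.10). Rnaseh2b, a subunit of the nuclease that removes RNA from DNA hybrids, rose by 2.47 ± 0.40, and Tlr9, the endosomal receptor for unmethylated DNA, fell by 2.64 ± 0.61 on the log2 scale (adjusted p 0.017 and 0.048). Neither call held without knockout library 1, with adjusted p of 0.067 and 0.21, and Tlr9 also missed the threshold with DESeq2 size factors or without haemoglobin and mitochondrial genes (adjusted p 0.056 and 0.051). Adjusted over the list alone, Rnaseh2b passed and Tlr9 did not. In the list, 4 members passed as higher and 8 as lower without wild-type library 1, and 3 and 6 without wild-type library 2. The same counts were 4 and 6 by DESeq2, 3 and 4 with no filter and 1 and 8 with library totals alone. Cgas, the cytosolic DNA sensor, had 4.51 ± 1.82 CPM in wild type and 6.77 ± 2.53 CPM in knockout (log2 fold change 0.59 ± 0.51, adjusted p 0.47). Tmem173, which encodes its adaptor STING, had 87.1 ± 37.2 and 47.5 ± 0.99 CPM (-0.87 ± 0.43, adjusted p 0.23, or 0.021 without wild-type library 2). The log2 fold changes of Ddx41 (-0.35), Tbk1 (-0.38), Irf3 (-0.14) and Irf7 (0.10) had adjusted p of 0.58 to 0.89. Irf7 had a negative value (-0.41) when scaled by library totals alone.

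Type I interferon-stimulated genes shifted down as a list, with 42 of 55 lower and a median of -0.57 (-0.80 between libraries 1, -0.50 between libraries 2). B, T and conventional dendritic cell markers had lower medians as well (-1.24, -1.11 and -1.11). For this list the camera adjusted p was 0.0031, and the adjusted p = 0.36 with an estimated correlation. Isg15, a ubiquitin-like protein, went against the list and rose from 33.6 ± 11.8 to 178 ± 92.5 CPM (log2 fold change 2.41 ± 0.52, adjusted p 0.039). Ifit1bl1 fell by 1.72 ± 0.38 on the log2 scale (adjusted p 0.043), and 0 members passed adjusted over the list alone. Without knockout library 1, Isg15 and Ifit1bl1 did not pass (adjusted p 0.24 and 0.47), nor did Ifit1bl1 without knockout library 2 (0.19). In contrast, 3 members passed as higher and 13 as lower without wild-type library 1, 4 and 14 without wild-type library 2, and 2 and 2 without knockout library 2. DESeq2 gave 4 and 14, edgeR with no filter 4 and 9, and library totals alone 2 and 16. Ifit1 (-0.19), Mx1 (-1.53), Isg20 (2.59) and Cmpk2 (1.44) had adjusted p of 0.78, 0.087, 0.052 and 0.065. Without wild-type library 1 or 2, Mx1 passed as lower (adjusted p 0.0048 and 0.026) and Isg20 as higher (0.0028 and 0.011), as did Cmpk2 (0.026 and 0.0081). Counts of all type I interferon genes summed to 0 and 2 in wild type and 2 and 6 in knockout, so their level was not measurable at this depth. A count of 0 allows up to 0.068 CPM in wild-type library 1. The list of interferons and their receptors had 6 tested members and did not shift (median -0.12, mean 0.029, camera direction down, adjusted p 0.76). Its members Ifnlr1 (1.49), Ifnar1 (-0.77), Ifng (-0.74) and Ifnar2 (0.44) did not pass, with Ifnar2 at -0.067 when scaled by library totals alone. Ifnlr1 passed as higher without wild-type library 2 (2.07, adjusted p 0.015) and ranged from 0.26 to 2.13 with 1 library left out.

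Interferon-gamma-induced genes were lower in 32 of 32 cases, with a median of -1.0 (-1.28 between libraries 1, -0.61 between libraries 2). Medians of B, T and conventional dendritic cell markers were lower too, at -1.24, -1.11 and -1.11. The camera adjusted p was 2.4e-06, and the adjusted p = 0.36 with an estimated correlation. Ciita, the activator of MHC class II transcription, fell by 2.16 ± 0.45 and the guanylate-binding protein gene Gbp10 fell by 3.24 ± 0.73 on the log2 scale (adjusted p 0.035 and 0.045), 6 genes falling adjusted over the list alone. Ciita did not pass without knockout library 1 (adjusted p 0.33), nor Gbp10 without knockout library 2 (0.11) or with DESeq2 size factors (0.051). In this list 12 and 13 genes passed as lower without wild-type library 1 or 2, and 1 and 3 without knockout library 1 or 2. By DESeq2 7 passed as lower, with no filter 5 and with library totals alone 11. NF-kB pathway genes were lower in 25 of 26 cases (median -0.97, camera adjusted p 6.2e-05, and adjusted p = 0.36 with an estimated correlation). By edgeR 0 passed over all genes (13 with an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom), with Map3k14 at -1.59 and Rel at -2.44. Of the 26 genes, 11 and 10 passed as lower without wild-type library 1 or 2, among them both of these, and 1 without knockout library 2 (Rel). The TRIM and ubiquitin regulator list had a median of -0.76 (camera adjusted p 0.0072, and adjusted p = 0.46 with an estimated correlation), with Trim14 at -1.77 and Rnf26 at 1.59 and 0 of 27 passing (11 with an unadjusted p under 0.05, 8 by DESeq2). Of these, 11 passed as lower and 2 as higher without wild-type library 1, 1 and 2 without wild-type library 2 (in both cases Trim14 and Rnf26 among them), and 1 and 0 without knockout library 2. MHC class II genes were lower in 16 of 16 cases (median -0.76, camera adjusted p 0.0046, and adjusted p = 0.53 with an estimated correlation), and only Ciita passed (2 genes adjusted over the list alone). MHC class I genes had a median of -0.40 (camera adjusted p 0.029, and adjusted p = 0.66 with an estimated correlation), with Nlrc5 at -1.82 and 0 of 22 passing (5 with an unadjusted p under 0.05, 3 by DESeq2, 1 by limma-voom). Without wild-type library 1 neither MHC list shifted, with medians of 0.11 for class I and -0.20 for class II and adjusted p of 0.50 and 0.21, although 3 members of each passed as lower. In the absence of wild-type library 2, 4 class I and 3 class II genes passed as lower. Nlrc5 passed in both cases (adjusted p 9.3e-04 and 8.9e-04). Without knockout library 2 their adjusted p were 0.14 and 0.090. With library totals alone 8 NF-kB, 8 TRIM and ubiquitin, 4 class I and 3 class II genes passed as lower, and with no filter 3, 3, 1 and 2. The B, T and conventional dendritic cell marker medians given above were lower than the medians of all these lists. Whether the falls of these lists go beyond those of the markers was not tested.

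Lymphocyte markers were lower. All 18 tested B cell genes had lower values in the knockout, with a median of -1.24 (-1.30 between libraries 1, -1.15 between libraries 2) and 0 passing over all genes by edgeR (13 with an unadjusted p under 0.05), 11 by DESeq2 and 0 by limma-voom, while 12 fell adjusted over the list alone. Camera gave an adjusted p of 4.9e-06, and the adjusted p = 0.36 with an estimated correlation. Pax5, which maintains B cell identity, had 535 ± 278 and 134 ± 30.02 CPM (adjusted p 0.069), and Fcer2a 454 ± 31.1 and 155 ± 14.6 CPM (adjusted p 0.070). All 21 T cell genes were lower, with a median of -1.11 (-1.38 between libraries 1, -0.88 between libraries 2), 0 passing over all genes by edgeR (16 with an unadjusted p under 0.05), 9 by DESeq2 and 1 by limma-voom, and 13 falling adjusted over the list alone. By camera the adjusted p was 4.7e-07, and the adjusted p = 0.36 with an estimated correlation. Lef1, a transcription factor of T cells, had a log2 fold change of -1.48 ± 0.37 (adjusted p 0.060) and Themis of -2.04 ± 0.50 (adjusted p 0.057). With 1 library left out, list medians ranged from -1.28 to -1.06 for B cells and from -1.31 to -0.86 for T cells. Log2 fold changes then ranged from -2.46 to -1.34 for Pax5 and -1.64 to -1.46 for Fcer2a. Those of Lef1 ranged from -1.57 to -1.38 and those of Themis from -2.53 to -1.33. With library totals alone 13 B cell and 12 T cell genes passed as lower, and with no filter 4 and 9. Germinal centre B cell genes had a median of -1.21 (camera adjusted p 0.0020, and adjusted p = 0.45 with an estimated correlation), with Bcl6 at -1.21 and 0 of 13 passing by edgeR against 5 by DESeq2. Effector and regulatory T cell genes had a median of -1.07 (camera adjusted p 2.5e-04, and adjusted p = 0.36 with an estimated correlation), with Ikzf2 at -2.68, 0 of 23 passing by edgeR (5 by DESeq2) and 2 falling adjusted over the list alone. Natural killer genes had a median of -0.46 (camera adjusted p 0.031, and adjusted p = 0.66 with an estimated correlation), with Il2rb at -1.19 and 0 of 22 passing by either tool. Members of these lists with an unadjusted edgeR p under 0.05 numbered 5, 8 and 4, all lower. Germinal centre genes passing as lower numbered 3, 8 and 3 without wild-type library 1, wild-type library 2 or knockout library 1. Effector T cell genes doing so numbered 6, 10 and 1 without wild-type library 1, wild-type library 2 or knockout library 2, Ikzf2 among them each time, and 3 natural killer genes did without wild-type library 2, Il2rb among them. Bcl6 passed without wild-type library 1 (adjusted p 0.012). Library totals alone gave 7 germinal centre, 7 effector T and 1 natural killer genes as lower, and no filter 1, 3 and 0. Marginal zone B cell genes (median -0.57, camera adjusted p 0.15, 0 of 12 passing) and plasma cell genes (median -0.50, camera adjusted p 0.10) did not shift. Within the plasma cell list Irf4 fell by 1.79 ± 0.40 on the log2 scale, with an adjusted p of 0.045 that was 0.47 and 0.14 without knockout library 1 or 2 and 0.050 with DESeq2 size factors, and 3 genes fell adjusted over the list alone. Plasma cell genes past the threshold numbered 3 higher and 3 lower without wild-type library 1, and 5 lower without wild-type library 2. Marginal zone genes that passed as lower numbered 3 and 1 there. Without wild-type library 2 the plasma cell list shifted down (median -0.99, camera adjusted p 3.3e-04), while its median was 0.57 without wild-type library 1.

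Dendritic cell genes were lower as well. Conventional dendritic cell genes had a median of -1.11 (camera adjusted p 0.0023, and adjusted p = 0.40 with an estimated correlation), with Itgax at -1.48, Itgae at -1.62, 0 of 19 passing by edgeR (10 with an unadjusted p under 0.05), 4 lower by DESeq2 and 4 falling adjusted over the list alone. Of the 19, 17 were lower, among them Batf3 (-0.18), Cadm1 (-0.15) and Xcr1 (-0.45), and Zbtb46 (0.88) and Sirpa (0.32) were higher. Its members Ccr7, which holds the median, and Cd8a are also in the T cell list, so the 2 falls are not independent. Plasmacytoid dendritic cell genes had a median of -1.17 (camera adjusted p 0.018, and adjusted p = 0.36 with an estimated correlation). Their 2 passing members went opposite ways, Tlr9 falling and Smim5 rising by 3.35 ± 0.49, while 5 fell and 1 rose adjusted over the list alone. Conventional dendritic genes passing as lower numbered 5 and 7 without wild-type library 1 or 2, Itgax and Itgae among them, and plasmacytoid genes 7 and 5. Scaled by library totals alone, 6 conventional and 8 plasmacytoid genes passed as lower, and with no filter 4 and 3. Without wild-type library 1, germinal centre B, effector T, natural killer and both dendritic lists did not shift (adjusted p 0.18, 0.052, 0.56, 0.10 and 0.15). Without knockout library 2 the natural killer and plasmacytoid lists did not (0.17 and 0.059). Monocyte (median 0.40) and splenic macrophage (median 0.34) genes did not shift (camera adjusted p 0.27 and 0.33, with 6 monocyte genes up and 3 down adjusted over the list alone), and both medians turned negative when scaled by library totals alone (-0.079 and -0.16). Vcan and F13a1, genes of classical monocytes, rose by 3.06 ± 0.51 and 2.53 ± 0.51, and F13a1 had an adjusted p of 0.057 without knockout library 2. Of the monocyte genes, 6 passed as higher and 2 as lower without wild-type library 1, and 3 and 3 without wild-type library 2. Macrophage genes that passed as higher numbered 3 and 1 there.

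**Figure D2:**
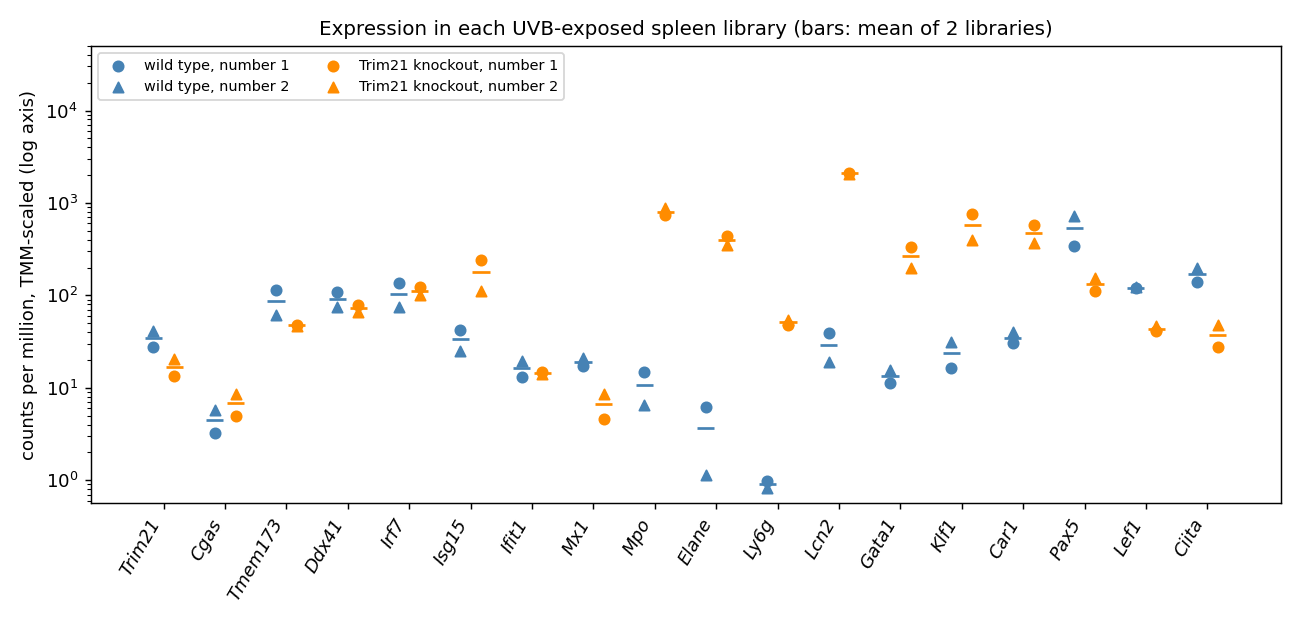
TMM-scaled CPM (log axis) of 18 genes in each library, blue for wild type and orange for knockout, circles for library 1 and triangles for library 2, with bars for means of 2 libraries. Mpo averaged 10.7 and 807 CPM in wild type and knockout, while Cgas averaged 4.51 and 6.77 CPM.

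Large falls are given for genes with an average log2 CPM of at least 1, so scarcer genes that fell further are left out. Col5a3, a fibrillar collagen chain, fell by 4.45 ± 0.76 on the log2 scale (4.93 ± 3.25 to 0.22 ± 0.086 CPM, adjusted p 0.018). Bach2, a repressor needed in B and T cells, fell from 110 ± 68.2 to 17.6 ± 6.22 CPM (adjusted p 0.038), Akap12 fell by 2.93 and Hivep3 by 2.76. Pdzd2, Nr4a3, Sorcs2 and Kcnc1 fell by 2.65, 2.65, 2.61 and 2.60, besides Gbp10 and Tlr9 above. Of these 10 genes, Col5a3 passed with each library left out, Gbp10 did not pass without knockout library 2, and the other 8 did not pass without knockout library 1 (adjusted p 0.061 for Akap12 to 0.24 for Nr4a3). Sorcs2 and Kcnc1 also missed it without knockout library 2 (0.091 and 0.10), and Pdzd2 with DESeq2 size factors or limma-voom (0.051 and 0.056).

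Mitochondrially encoded mRNAs were lower in 12 of 13 cases, with a median of -0.62 and 0 passing by edgeR (2 with an unadjusted p under 0.05, 3 by DESeq2; camera adjusted p 0.036, and adjusted p = 0.52 with an estimated correlation). Values for mt-Nd4l and mt-Cytb were -1.78 and -1.02, and mt-Nd4l passed without wild-type library 1 (-2.34, adjusted p 0.0013). Mitochondrial genes took 9.55% ± 1.05 of wild-type counts and 4.52% ± 0.73 of knockout counts (SD, n = 2), and their list did not shift without wild-type library 1 or knockout library 2 (adjusted p 0.10 and 0.19). Immediate-early and heat-shock genes did not shift (median -0.12, camera adjusted p 0.21), although Egr1 fell by 2.10 ± 0.41 on the log2 scale and Nr4a3 fell too (4 genes falling adjusted over the list alone). Without wild-type library 2 that list shifted down (median -0.52, adjusted p 0.014), and Egr1 had an adjusted p of 0.33 and 0.063 without knockout library 1 or 2. In this list 3 members passed as higher and 4 as lower without wild-type library 1, and 1 and 8 without wild-type library 2. Across genes, log2 fold change had a Spearman correlation of -0.34 with exon length, where genes are not independent replicates, so short transcripts were higher in the knockout on the whole. Whether this trend contributes to the lists that shifted down was not tested.

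The DNA damage and p53 list did not shift (median -0.25, camera adjusted p 0.75). Gadd45a rose by 2.97 ± 0.44 and Psrc1 by 2.60 ± 0.44, and Psrc1 had an adjusted p of 0.094 without knockout library 1. Unfolded protein response genes did not shift (median 0.12, or -0.36 when scaled by library totals alone, camera adjusted p 0.50), and only the asparagine synthetase gene Asns rose (3.95 ± 0.42, adjusted p 0.011). With wild-type library 1 left out, 5 p53 list members passed as higher and 5 as lower, against 7 and 2 of the unfolded protein response. Endothelial and stromal genes (median -0.72, camera adjusted p 0.17) had 0 of 22 passing by edgeR (6 with an unadjusted p under 0.05, 4 by DESeq2). Haematopoietic progenitor genes (median -0.47, mean 0.11, camera direction down, adjusted p 0.75) included Cd34, which rose by 2.97 ± 0.57 and had an adjusted p of 0.092 without knockout library 2 (1 up and 1 down adjusted over the list alone). Stromal genes past the threshold numbered 2 higher and 1 lower without wild-type library 1, and 3 and 1 without wild-type library 2. For progenitor genes these counts were 3 and 2, and 2 and 2. The pancreas and adipose list and the skin list each had 3 tested members and were not tested.

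Genes around Trim21 were counted as a check on DNA linked to the targeted allele. Within 10 Mb, 9 of 144 tested genes passed, against 842 of 13387 elsewhere (odds ratio 0.99, 95% interval 0.44 to 1.95, 2-sided Fisher's exact test p = 1). The fixed list of neighbours (63 tested, median 0.019, mean 0.0040, camera direction down, adjusted p 0.69) did not shift. In it Rrm1, a ribonucleotide reductase subunit, rose by 2.63, Stard10 by 3.16 and Folr1 by 4.57, and Art2b fell by 2.35 on the log2 scale (adjusted p 0.047). Art2b did not pass without knockout library 1 or 2 (adjusted p 0.072 and 0.14), with DESeq2 size factors, with limma-voom, or without haemoglobin and mitochondrial genes. Of the 63 neighbours, 13 passed as higher and 13 as lower without wild-type library 1, and 7 and 5 without wild-type library 2.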

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

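These values, computed within each replicate number, were chosen after the data were seen, and the differences between numbers were not tested, since each number holds 1 library per genotype. The plasma cell list stood out because the numbers moved opposite ways: its median log2 fold change was -0.86 between the libraries numbered 1 and 0.21 between those numbered 2. The immediate-early and heat-shock list stood out for the same reason, with medians of -0.40 and 0.34.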

How the results depend on the processing

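Library totals alone and values within numbers were alternatives chosen after the data were seen. The number of genes past the threshold was 851 (798 higher, 53 lower in the knockout). It was 2468 (1567, 901) by the DESeq2 Wald test, 1768 (1278, 490) with no filter, 2158 (782, 1376) with library totals alone and 1931 (1373, 558) at an adjusted p under 0.1. Falls numbered 16 in a test against a fold of 1.5. With 1 library left out, the lone library being assumed to vary like the other genotype's, it ranged from 631 to 4347 (601 to 2300 higher, 30 to 2047 lower), and 537 of the 851 genes passed without knockout library 1. With the replicate number as a block, it was 5705 (3036, 2669). Same-numbered libraries deviated together (correlation across genes 0.46), but the labels give no pairing, so the numbers were not taken to pair the mice. Same-numbered libraries also shared the male or female pattern of Xist and Y-linked counts, which was thus balanced over the genotypes. Differences between numbers stayed in the residual spread of the main fit (common dispersion 0.14, against 0.061 with the block). A list with 0 genes passing in the main fit is therefore weak evidence of no change. With the block, 15 of 18 B cell, 18 of 21 T cell, 20 of 32 interferon-gamma and 16 of 26 NF-kB genes passed as lower, as did Tmem173 (-0.81, adjusted p 0.020). Of the type I interferon-stimulated genes, 5 then passed as higher and 23 as lower, and of the DNA-sensing genes 6 and 13. The cause of these differences was not tested.

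Lists shifted up numbered 5 in every alternative with the preset correlation except no filter (6, the megakaryocyte list added). Lists shifted down numbered 14, and 6 to 16 with 1 library left out. With an estimated correlation 0 and 0 lists passed, and by fry 0 and 0 (lowest adjusted p 0.36 and 0.069, with 1 and 13 lists at an unadjusted p under 0.05). Trim21 passed with the replicate block (-1.03, adjusted p 0.0029) and ranged from -1.35 to -0.72 with 1 library left out (adjusted p 0.020 to 0.89).

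The odds ratio of calls within 10 Mb of Trim21 (0.99) had p over 0.05 in each setting. It lay above 1 in several: 1.44 by DESeq2, 1.30 with no filter, 1.02 at 1 CPM in 2 libraries, 1.30 with the block, 1.22 with library totals alone, 1.30 within 5 Mb, and 1.15 to 1.31 with 1 library left out. It lay below 1 with DESeq2 size factors (0.83), limma-voom (0.89), non-robust dispersion (0.98), no haemoglobin or mitochondrial genes (0.81) and within 20 Mb (0.75). The direction of a list is that of camera or fry, so a median need not change sign with it. Other results that turned direction were past the threshold in neither setting, except MHC class I presentation, whose median was 0.019 within number 2. With no filter, interferons and receptors had a median of 0.15 and progenitors of -0.090. By fry the p53 list (-0.25) and the Trim21 neighbours (0.019) turned. With library totals alone Irf7 was -0.41 and Ifnar2 -0.067. With 1 library left out, medians ranged from -0.22 to -0.025 for interferons and receptors, -0.44 to 0.29 for inflammatory cytokines, -0.064 to 0.44 for the unfolded protein response, -0.99 to 0.57 for plasma cells, -0.49 to 0.065 for progenitors, 0.10 to 0.28 for the lupus list and -0.27 to 0.17 for the neighbours. Log2 fold changes then ranged from -0.76 to 0.11 for Tbk1, -0.47 to 0.27 for Irf3, -0.26 to 0.58 for Irf7 and -0.46 to 0.13 for Ifit1. Over the named genes other than Trim21, calls were lost 37 times across the alternatives, 19 of them without knockout library 1, and gained 356 times, most often with the block (83).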

Other observations

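Genes linked to lupus and to clearance of dying cells had no common direction in the knockout (27 tested, median 0.012 by TMM and -0.41 by library totals, camera adjusted p 0.77), with 3 rising and Tlr9 falling (11 passing as higher and 4 as lower without wild-type library 1, 4 and 5 without wild-type library 2). Adjusted over the list alone, 5 rose and 4 fell. The B cell survival factors Tnfsf13b (BAFF) and Tnfsf13 (APRIL) rose by 3.52 ± 0.64 and 2.60 ± 0.40 on the log2 scale, and complement C3 by 2.65 ± 0.43 (edgeR adjusted p 0.022, 0.015 and 0.017). Tnfsf13b was scarce, at 0.38 ± 0.20 and 4.35 ± 0.98 CPM (SD, n = 2), whereas C3 reached 260 ± 76.5 CPM. Of 21 tested inflammatory cytokines and chemokines, only Tnfsf13b passed (median -0.13, camera adjusted p 0.55), and Lif (-3.14), Il12a (-1.31) and Tnfsf11 (-1.46) did not. In this list 3 members passed as higher without wild-type library 1 and 1 as lower, Il12a (-1.44, adjusted p 0.047).

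The tests below were chosen after the results were seen, except those of gene length with GC and of overlapping exons. Higher neutrophil and erythroid transcripts in the knockout were weighed first. Scaling distorted by haemoglobin-rich libraries would move all genes alike, but the erythroid median, the lower of the 2 lists, exceeded the median of all genes by 3.21. A length and GC trend is argued against for these 2 lists by a neutrophil median of 4.36 after its removal (erythroid 3.21). Lists that shifted down were not corrected in this way, so the trend stays open for them. Within these 2 lists retained blood cannot be told apart from cells of the spleen. Primary granule genes, made in promyelocytes, had a median 2.48 above the other 22 neutrophil list members, but the ranges overlapped (lowest 6.24 against highest 6.52). A set of mature circulating neutrophil genes had a median of 1.63, with 1 of 7 passing, but left out S100a8 and S100a9 (4.95 and 4.82). Erythroid transcription factors with Epor had a median of 4.30, with 4 of 4 passing, and globins 2.58, with 0 of 4. These sets were drawn up after the values were seen, so no conclusion is drawn from them. The cell cycle list, fixed beforehand, was higher in 40 of 40 cases with 34 passing. Its median stayed at 2.59 to 3.08 with 1 library left out. Mature neutrophils and red cells do not divide, so these values argue against retained mature blood as the source of the cell cycle rise. They do not show which cells the neutrophil and erythroid transcripts came from. Whether genotype, length of UVB exposure or another difference between these few animals lies behind the rise was not tested.

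Trim21 counts that remain in the knockout were weighed next. The fall in Trim21 differed from the B cell median by only 0.22 on the log2 scale, under its SE of 0.42. A smaller lymphocyte share alone was thus not excluded. With so wide an SE, and no measure of Trim21 by cell type, the comparison cannot decide whether it accounts for the fall. Transcript from exons left in the targeted allele cannot be told apart from intact transcript, because the table holds a single count per gene and the lowest knockout count was 345.

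Finally, 15 genes had at most 3 counts in both libraries of a genotype and at least 30 in both of the other, limits set after the data were seen. Of these, 6 were detected in wild type, such as Gm10778 (177 and 326 counts against 0 and 2), and 9 in knockout, such as the embryonic globin Hba-x (0 and 0 against 30 and 43), both picked after their values were seen. Strain DNA within 10 Mb of Trim21 could not explain most of them, as 0 of 15 lay there. This allows a share of up to 21.8% (exact 95% limit, taking the genes as independent). Strain DNA farther along the chromosome or on other chromosomes was not tested. Reads shared with an overlapping gene may contribute: 2 of 15 had same-strand exon overlap against 4.17% of other genes (odds ratio 3.54, Fisher's exact test p = 0.13), too few to decide.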
